A study of Homo sapiens with 2 samples.

How the data were processed

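DNA methylation was measured by reduced representation bisulfite sequencing (RRBS) in HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen. RRBS cuts DNA with MspI, which recognises CCGG whatever the methylation of the inner cytosine, selects short fragments and so enriches CpG-rich sequence. Bisulfite converts unmethylated cytosines to uracil, which is read as thymine, and leaves methylated cytosines as they are. Cytosines with a 5-hydroxymethyl group also resist conversion, so the method counts both forms together. There were 2 libraries, 1 from untreated cells (control) and 1 from cells treated with hydrogen peroxide (H2O2), an oxidant. The labels give no dose or time for the treatment. Per the labels, the digested DNA was end-repaired and joined to methylated adapters. Fragments of about 40 to 220 bp were then cut from a gel, treated with bisulfite over 2 rounds, amplified and sequenced on an Illumina HiSeq instrument.

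The deposited files hold, for each cytosine, whole-number counts of methylated and unmethylated reads that the authors made from their alignments. The files have no header, so the meaning of the columns was read from the values: non-CpG cytosines had almost all of their reads in 1 of the count columns, which was taken as unmethylated. The submitters' processing notes name the hg19 genome build, CASAVA 1.8 and FastQC. The aligner, the methylation caller, the filters and the treatment of duplicate reads are not given in the sources used here. A further deposited column holds a score of unstated meaning, which is 0 where no read lies and at least 1 elsewhere, and which looks like the mean number of genome matches of the reads. It was used only to class sites as exactly 1, above 1 and up to 10, or above 10. A last deposited column of other, unstated content was not used.

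Both files list the same 41227555 cytosines in the same order. These cytosines could be arranged into 657814 complete MspI fragments. The CpG of the MspI site itself is not among them, and 0 listed CpGs lie inside a listed CCGG, so cytosines filled in during end repair at the cut did not enter the CpG levels. Reads of both strands of a CpG were summed. The analysed CpGs had at least 10 reads in each library, lay on the autosomes or X, and were not among the top 0.1% by coverage in either library. All positions are 1-based hg19 coordinates as the files give them.

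The methylation level is the share of methylated reads. The global difference is the mean over CpGs of the H2O2 level minus the control level, with the pooled share of methylated reads beside it. Single CpGs were compared by a two-sided Fisher's exact test of methylated and unmethylated reads with Benjamini-Hochberg adjustment over all tested CpGs. A CpG was called at an adjusted p under 0.05 and a difference of at least 20 percentage points. Regions were compared in the same way on reads summed over windows of 1 kb with at least 5 analysed CpGs, and called at a difference of at least 10 points. The 5 called CpGs with the largest rise and the 5 with the largest fall are named. For windows, the 10 largest in each direction among those with at least 100 reads in each library are named. These rules, the tests and the thresholds were set before the data were examined.

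The planned regions were promoters, other annotated features and 19 gene lists, among them DNA repair pathways and TET enzymes. The gene table at hand is for another genome build than hg19, and coordinates were not converted, so promoters, annotated features and gene lists were not analysed here. The windows took the place of promoters, as had been laid down for this case. CpG-dense fragments, with a GC content of at least 50% and an observed-over-expected CpG ratio of at least 0.6, took the place of CpG islands. The minimum length planned for islands was not required of these fragments. The median length of all rebuilt fragments was 102 bp.

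With 1 library per group there is no replicate. Each test compares the reads of 2 libraries and not the conditions. Intervals are 95% Wilson intervals for a share of reads or CpGs and normal intervals for mean differences. Where a count is 0, the limit given is 3 reads of the total. Intervals and limits cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Reads also cover several CpGs of a fragment at once, and reads of a window are sums over its CpGs. A read thus counts once for each CpG it covers, so the p of a window is too small and its interval too narrow. As a substitute for replicates, the plus and minus strands of a CpG, which are read from different molecules, were used as separate measurements within each library. Standard errors of means over many CpGs came from leaving out 1 chromosome at a time (jackknife).

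The tests were checked on simulated counts at the real depths. Counts were drawn independently for each CpG, without reads shared by CpGs and without PCR copies. Of 200 simulated single CpGs changed by 20, 40 and 60 points, 2.5%, 34.5% and 70.5% were called, with 0 calls among 1952079 unchanged CpGs. In 200 windows each CpG was changed by 20 points, down at higher levels and up at lower ones. Such changes can cancel in windows of mixed levels. Of these windows 86.0% were called, but so were 277 of 116794 unchanged windows. In these, fragments of different methylation inside a window had gained or lost coverage between the libraries. A test that weights each CpG alike in both libraries (Cochran-Mantel-Haenszel, CpGs as strata) was therefore added after the data were examined. It called 83.0% of the windows with CpGs changed by 20 points and 0 unchanged windows, and its results stand beside those of the planned test.

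Alternatives covered coverage minimums, the upper coverage limit, thinning to equal depth, strands kept apart, pooling, thresholds, the weighting of CpGs and the size of regions. The analysis used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, Numba 0.67.0, PyArrow 21.0.0 and Matplotlib 3.10.9.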

Results

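The series concerns a TET1-based complex and the control of DNA repair genes under oxidative damage, and these libraries address whether H2O2 treatment changed DNA methylation in HEK293T cells. TET1 oxidises 5-methylcytosine and thereby starts its removal. RRBS was available for 1 control and 1 H2O2 library. Reads summed over all listed cytosines came to 582087575 in the control library and 564721508 in the H2O2 library. At CpGs these sums were 81896537 and 79725887. Of 2788983 listed CpGs, 2092496 had at least 10 reads in the control library and 2029457 in the H2O2 library. The analysed set held 1952679 CpGs in 412579 MspI fragments. Median coverage was 33 reads in both libraries, with means of 38.9 and 38.1 reads. Coverage correlated across CpGs with a Spearman rho of 0.843, although CpGs are not independent replicates.

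CpG methylation was nearly equal in the untreated and treated cells. The mean level was 62.1% in the control and 61.9% in the H2O2 library, a difference of -0.190 percentage points (95% interval -0.200 to -0.180, counting error). The median difference was 0. In the control library 31.0% of CpGs lay below 20% methylation, 10.1% between 20 and 80%, and 58.9% above 80%. The corresponding shares in the H2O2 library were 31.1%, 10.2% and 58.7%. Levels correlated across CpGs with r = 0.987 and 89.0% of CpGs differed by at most 10 points. Only 8 CpGs went from below 20% in the control library to above 80% in the H2O2 library, and 28 went the opposite way. Counts drawn around a common level at the same depths gave 2 and 1 such CpGs, with binomial sampling error only. Pooling all reads gave a larger difference, with 61.8% of control reads and 58.6% of H2O2 reads methylated. With the control library's coverage as weights for both libraries this difference was -0.190 points, 6.12% of its pooled size.

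**Figure D1:**
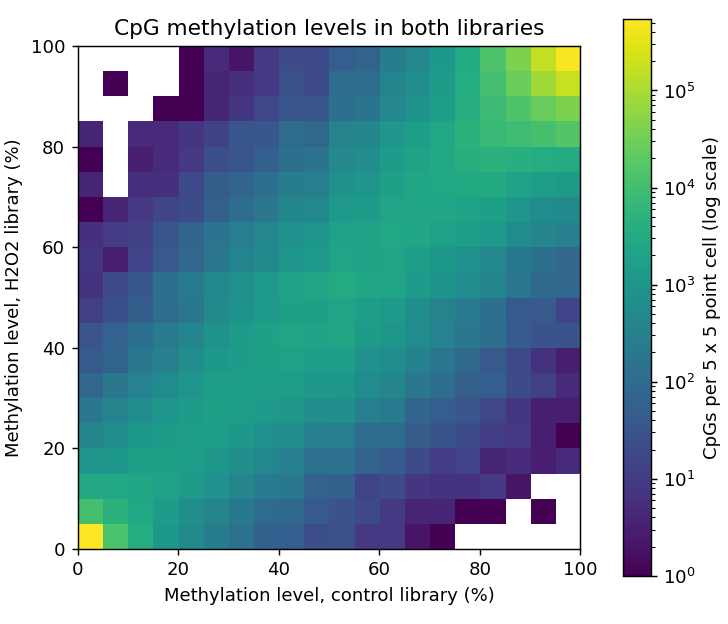
Methylation level of each analysed CpG in the control library (horizontal axis, %) and in the H2O2 library (vertical axis, %), as the number of CpGs in cells of 5 by 5 points on a logarithmic colour scale. Most CpGs lie in the corners of low or high methylation in both libraries, and 89.0% differ by at most 10 points.

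The small difference had the same sign in each class of sequence and on each chromosome examined. CpG-dense fragments, a loose stand-in for CpG islands, averaged 47.2% in the control and 47.0% in the H2O2 library over 1035104 CpGs (-0.227 points, jackknife SE 0.0119). In the control library 47.7% of these CpGs lay below 20% and 44.7% above 80%, so the mean is not the level of islands. The remaining fragments averaged 79.0% and 78.8% over 917575 CpGs (-0.148 points, SE 0.00797). Among CpGs with a score above 10, which look like repeated sequence, the levels were 86.9% and 86.8%. Where the score was exactly 1 in both libraries, they were 57.6% and 57.4%. Per chromosome the difference ran from -0.129 points on chromosome X to -0.264 points on chromosome 2. On chromosome 21, the most methylated chromosome analysed, levels were 67.3% and 67.1%. Chromosome 3, the least methylated, had 59.1% and 58.9%. Over 2336 bins of 1 Mb, the differences measured on the plus and on the minus strand had r = -0.0220 (two-sided permutation p = 0.288).

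Few reads outside CpGs were methylated. Of reads at CHG and CHH cytosines (H is A, C or T), 0.130% were methylated in the control library (95% interval 0.130 to 0.131) and 0.125% in the H2O2 library (0.125 to 0.125). These values are upper bounds on the share of unmethylated cytosines that stayed unconverted. The 15946 cytosines with at least 10% methylated reads held 44.8% and 45.7% of the methylated non-CpG reads, and without them the levels were 0.0720% and 0.0680%. CHG cytosines had 0.105% and 0.102%, CHH cytosines 0.143% and 0.137%. By trinucleotide, CAC with 0.276% and 0.254% and CAT with 0.269% and 0.256% were above the others. CTG had 0.0597% and 0.0586%, and CCA had the lowest levels with 0.0526% and 0.0504%.

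Single CpGs that differed between the libraries were rare. Fisher's exact test called 14 of 1952679 CpGs, 8 higher and 6 lower in the H2O2 library, and the smallest adjusted p was 0.00214. The largest rise was at 160385883 on chromosome 1, from 41.3% of 75 control reads to 92.5% of 40 H2O2 reads (95% intervals 30.9 to 52.6% and 80.1 to 97.4%). At 2457364 on chromosome 19 the level rose from 42.4% of 66 reads to 84.8% of 79 reads. The CpG at 20460606 on chromosome 17 rose from 30.9% of 110 reads to 70.8% of 96 reads. On chromosome 5, position 1201713 rose from 53.0% of 66 reads to 92.4% of 79 reads. The CpG at 1322630 on chromosome 2 rose from 63.1% of 65 reads to 100% of 72 reads and had the lowest p.

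The largest fall of a single CpG was at 33197638 on chromosome 22, from 90.9% of 22 reads (95% interval 72.2 to 97.5%) to 20.0% of 35 reads. The other 5 CpGs of its fragment together went from 75.2% to 25.5%. At 143575306 on chromosome 8 the level fell from 57.5% of 87 reads to 18.1% of 83 reads. On chromosome 20, position 31349747 fell from 58.2% of 122 reads to 22.8% of 92 reads. The CpG at 28634521 on chromosome 16 fell from 85.0% of 107 reads to 52.4% of 105 reads. At 115909921 on chromosome 5 the level fell from 31.6% of 57 reads to 0 of 62 reads, which allows a level of up to 4.84% by the limit of 3 reads and up to 5.83% by the Wilson interval. All 14 CpGs lay in fragments of 68 to 99 bp. Mean coverage in the control and H2O2 libraries was highest at 80 to 120 bp, with 55.5 and 58.7 reads. It was 38.7 and 38.8 reads at 40 to 80 bp and 20.0 and 15.7 at 200 to 220 bp. Calls need depth, and whether this accounts for the fragment lengths was not tested. In 12 of the 13 fragments with other analysed CpGs, those CpGs differed in the same direction, by at least 10 points in 7. CpGs of a fragment share reads, so this is not independent support. Next to the named rises on chromosomes 19 and 2 the other CpGs rose by 18.3 and 19.2 points. On chromosomes 1, 17 and 5 they rose by 4.29, 1.45 and 0.212 points. They fell by 23.4 and 22.3 points at the named falls on chromosomes 20 and 16, but rose by 1.13 points at 115909921.

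The count of 14 depended on the settings. It was 6 with a minimum of 5 reads, 20 with a minimum of 20 reads, 27 without an upper coverage limit, 1 at equal depth, 7 with strands kept apart, 1 at an adjusted p under 0.01 and 24 at a score of exactly 1. In the simulation 200 CpGs of each size were changed among 1952679. Where changes are that rare, most differences of 20 points would be missed at this depth, since 2.5% of those simulated were called. The p needed after adjustment depends on how many CpGs change, so this share does not hold for widespread changes. An unadjusted Fisher p under 0.05 was found at 2.60% of CpGs, against 1.06% among counts drawn without any difference. The drawn counts held binomial sampling error only. The variance of the measured differences was 1.31 times the binomial one. It was 1.19 times at CpGs with 20 to 50 reads in both libraries together and 1.98 times with 200 to 500. The size of this excess alone does not tell differences of the cells from reads that are not independent. The strand comparison below bears on differences that both strands of a CpG share. The covariance of strand differences there had an upper 95% limit of 0.346 squared points, or 1.06 with at least 20 reads per strand.

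The strands of a CpG differed more often within a library than the libraries did. Over 783934 CpGs with at least 10 reads on each strand in each library, the same test called 894 CpGs between the strands of the control library and 673 between those of the H2O2 library. Between the libraries it called 4 CpGs from plus-strand reads and 4 from minus-strand reads. Of these 8 CpGs, 3 had the same sign on the other strand. Calls between strands include strand bias and methylation of a single strand, which can recur in both libraries and then cancel between them. The counts within and between libraries are therefore not like measures of noise. Of the 14 CpGs called on summed reads, 13 were read on both strands in both libraries, and in all 13 the strands differed in the same direction, although these CpGs were selected on the sum of both strands. Across CpGs, the H2O2-minus-control differences on the plus and minus strands had r = -0.000412 and rho = -0.00125. Their covariance was -0.0269 squared points (jackknife SE 0.190). With at least 20 reads per strand, which left 176100 CpGs, r turned to 0.00729 (95% jackknife interval -0.00687 to 0.0215).

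Among 117194 windows of 1 kb, the planned test on summed reads called 237 higher and 638 lower in the H2O2 library, 875 in all. These are 0.202% and 0.544% of windows. In both libraries 79995 windows lay above 80% and 19140 below 20%, and 0 windows moved between these classes. Window levels correlated with r = 0.995, and 98.1% of windows differed by less than 10 points. Of the called windows, 731 had between 20 and 80% methylation in the control library. Counts drawn without any difference at the same depths still gave 257 calls, 63 higher and 194 lower. With each CpG weighted alike in both libraries, 147 windows were called higher and 343 lower, and drawn counts gave 0 calls. The drawn counts were independent from CpG to CpG, while real reads cover several CpGs and may include PCR copies. They therefore do not give the rate of false calls in real data. Of the 875 windows, 407 were called by both tests in the same direction.

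Among windows with at least 100 reads in each library, summed over CpGs, the largest rise was at 26570001 to 26571000 on chromosome 6. It went from 29.3% of 150 CpG reads to 75.5% of 110 (95% intervals 22.6 to 37.1% and 66.6 to 82.5%). These sums came from 6 CpGs of 1 MspI fragment, so the same reads count repeatedly and the intervals are too narrow. The next window on that chromosome, 26571001 to 26572000, rose from 29.4% to 59.3%. On chromosome 16, the window 15528001 to 15529000 rose from 26.5% of 574 reads to 66.5% of 352 reads at 25 CpGs, all of them higher. Other rises on chromosome 16 were at 21171001 to 21172000, from 49.2% to 76.2%, and at 82077001 to 82078000, from 38.0% to 62.5%. The window 53961001 to 53962000 on chromosome 3 rose from 26.5% to 58.7%, with -19.8 points on the plus and 55.2 on the minus strand. Chromosome 6 held further rises at 85474001 to 85475000, from 19.8% to 47.9%, and at 151647001 to 151648000, from 42.3% to 68.9%. On chromosome 17 the window 73056001 to 73057000 rose from 51.8% to 78.9%. On chromosome 7 the window 94138001 to 94139000 rose from 32.8% to 59.2%. Some adjacent windows went the other way on the plus strand. From plus-strand reads alone, 85473001 and 151646001 on chromosome 6 and 94139001 on chromosome 7 were called lower, by -15.7, -26.1 and -13.5 points. Their minus-strand differences were 18.3, 26.9 and -0.530 points.

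The largest fall among windows of that depth was at 115818001 to 115819000 on chromosome 9, from 85.2% of 176 reads to 36.6% of 186 reads (95% intervals 79.2 to 89.7% and 30.0 to 43.7%). The window 121844001 to 121845000 on chromosome 4 fell from 72.0% of 271 reads to 31.0% of 445 reads, with all 14 CpGs lower. On chromosome 14, the window 61787001 to 61788000 fell from 61.3% to 24.1%, with 3 of its 5 CpGs lower and 2 higher. Its difference was -39.5 points on the plus and 8.03 on the minus strand. Another on chromosome 14, 36278001 to 36279000, fell from 30.9% of 679 reads to 4.18% of 502 reads, with 12 of its 27 CpGs lower and 1 higher. Chromosome 7 had a fall from 57.7% to 22.4% at 105221001 to 105222000. Chromosome 20 had one from 58.1% to 27.6% at 8112001 to 8113000. On chromosome 1 the window 153537001 to 153538000 fell from 40.9% to 11.6%. On chromosome 2 the window 52667001 to 52668000 fell from 61.9% to 34.1%. On chromosome 13 the window 20692001 to 20693000 fell from 49.8% to 22.8%. The window 5052001 to 5053000 on chromosome 4 had 79.6% and 52.8%, but 71.3% and 62.7% with each CpG weighted alike. It was the only 1 of the 20 named windows that the equally weighted test did not call.

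Of the 20 named windows, 13 rested on a single MspI fragment. The window 82077001 to 82078000 on chromosome 16 reached a score of 740.2 and the window 52667001 to 52668000 on chromosome 2 a score of 19.4, which look like repeated sequence. In 5 of the 19 read on both strands, the strands differed between the libraries in opposite directions. The window at 82077001 was among them, with 25.1 points on the plus and -17.3 on the minus strand. Of all called windows with at least 100 reads, 816 were read on both strands, and in 701 both strands lay in the called direction, although these windows were selected on the sum of both strands. When only the deepest CpG of each window was tested, so that each read counted at most once, 3 windows were called. This also leaves far fewer reads than the median of 308 control reads per window, so fewer differences can be called. The 2 effects were not separated.

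Window differences found on one strand had on average no counterpart on the other. In 53513 windows measured on each strand, 613 were called from plus-strand reads and 600 from minus-strand reads. In the 613 windows the mean plus-strand difference in the called direction was 18.1 points, while the minus-strand difference was -0.238 points. The ratio of these means was -0.0132 (jackknife SE 0.0238). On the minus strand 51.7% (SE 2.02) of these windows had the same sign. Both strands called 121 windows, of which 60 had the same direction, where independent lists of this length would share 6.87. The equally weighted test gave a ratio of -0.0455 (SE 0.0283) over 446 windows. In simulated counts with changes of 10 and 20 points on both strands of 200 windows each, this ratio was 0.408 by the planned test, which also called unchanged windows, and 0.916 by the equally weighted test. Between the strands of a single library, the planned test called 1912 windows in the control and 1601 in the H2O2 library. The equally weighted test called 923 and 841.

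**Figure D2:**
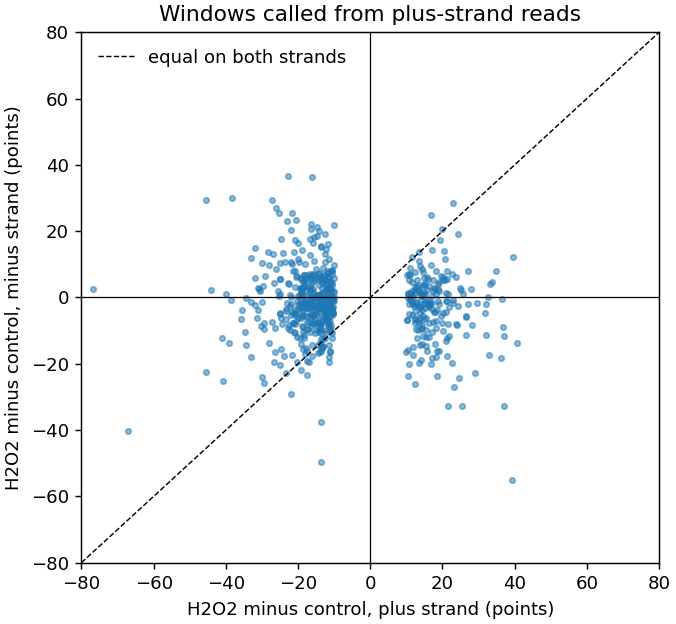
H2O2-minus-control difference in percentage points on the plus strand (horizontal axis) and on the minus strand (vertical axis) for the 613 windows of 1 kb called from plus-strand reads alone. Each point is a window and the dashed line marks equal differences; the minus-strand differences scatter around 0, with a mean of -0.238 points in the called direction.

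CpGs of intermediate methylation had lower levels in the H2O2 library, in a comparison added after the data were examined. CpGs at 20 to 60% on one strand, measured on the other, averaged 44.6% in the control and 43.2% in the H2O2 library, a difference of -1.37 points (jackknife SE 0.115). At 95% or more on one strand the levels were 96.0% and 95.9%. For CpGs at 20 to 60%, the difference was -0.371 points (SE 0.247) where the fragment held 1 CpG and -3.24 points (SE 0.428) where it held 11 or more. Coverage differed along the same classes. In fragments with 11 or more CpGs, the H2O2 library had 0.879 times the control coverage at CpGs above 80% and 1.10 times at CpGs below 20%. With 1 CpG these ratios were 0.970 and 0.980. By fragment length, the coverage ratio was 1.06 at 80 to 120 bp and 0.788 at 200 to 220 bp.

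**Figure D3:**
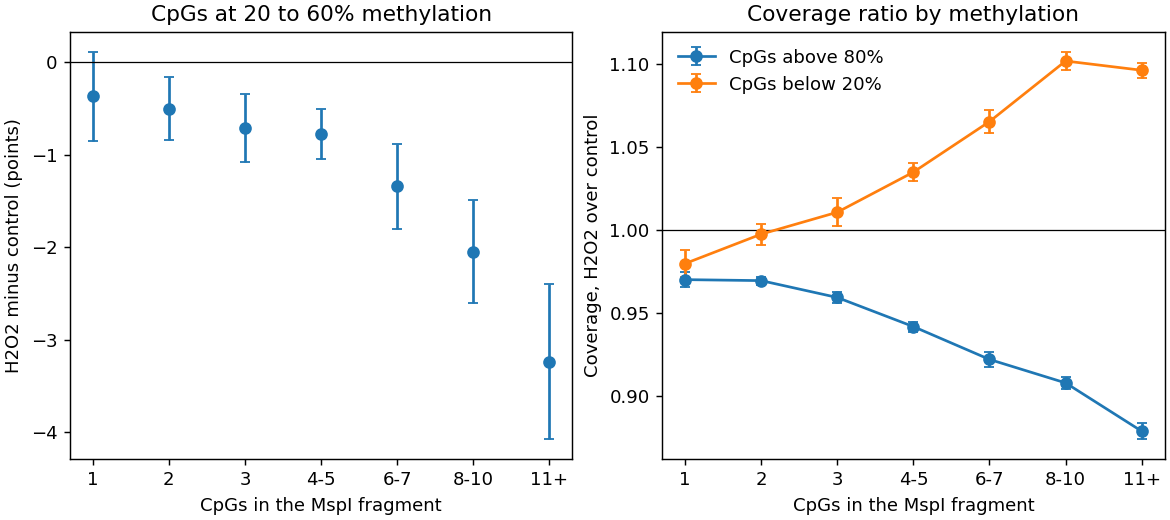
Left, H2O2-minus-control difference (percentage points) of CpGs at 20 to 60% methylation by the number of CpGs in their MspI fragment. Right, coverage of the H2O2 library over that of the control library (ratio) for CpGs above 80% and below 20%; points are means or ratios over CpGs and bars are 95% jackknife intervals over chromosomes, and the left difference grows from -0.371 to -3.24 points.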

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

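Settings not planned before the data were examined were the score of exactly 1, the equal weighting of CpGs, windows of 500 bp and 2 kb, and single MspI fragments. The global CpG difference kept its sign in 7 alternatives and stayed within its interval in 6, while pooling all reads gave -3.11 points. The count of differing CpGs, 14, was 6 at 5 reads, 27 with no upper coverage limit, 1 with counts thinned to equal depth, 7 with strands apart, 1 at an adjusted p under 0.01 and 24 at a score of exactly 1. Of the 14 CpGs, 6 were called again at 5 reads, 14 with no upper limit and 1 after thinning. The count of windows, 875, was 307 after thinning, 3 with only the deepest CpG, 462 with unweighted means, 1882 at 5 points, 120 at 20 points and 490 with CpGs weighted alike. Single fragments gave 1633, and 1907 with CpGs weighted alike. In 6 of the 14 window alternatives the count stayed within 1.5 times. The non-CpG difference, -0.00510 points, was -0.00432 at 20 reads. At 20 reads per strand, the strands differed at 508 CpGs in the control and 401 in the H2O2 library, and the correlation of strand differences was 0.00729 (-0.00687 to 0.0215). Stricter thresholds leave fewer eligible sites by construction, and the deepest CpG alone leaves fewer reads per window. Thinning leaves fewer reads and also evens the depth of the libraries, and these effects were not separated. The cause of the other changes was not tested. Each of the 7 sequence classes kept its negative difference at 20 reads. Depth limits the calls of single CpGs, as 34.5% of simulated changes of 40 points, which were rare among all CpGs, were called. Leaving out CpGs inside MspI sites had been planned and was not run, since 0 such CpGs are listed. The planned settings for promoter width, gene lists and all annotated genes were not run either, since annotated features were not analysed here. No paired analysis was possible because each group has 1 library.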

Other observations

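The tests on CpG number, bisulfite conversion, fragments with 1 CpG, coverage weighting, the covariance of CpG strands and fragment ends were chosen after the results they measure were seen, and the tests on windows by strand and on the neighbouring cytosine before.

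Coverage by chromosome was uneven in the same way in both libraries. Chromosome 8 had means of 52.6 and 51.6 reads per analysed CpG in the control and H2O2 libraries, chromosome 17 had 46.3 and 45.4, and chromosome X had 23.4 and 23.1. Mitochondrial DNA was almost free of methylated reads. At its 14 listed CpGs 1.07% of 162143 control reads (95% Wilson interval 1.02 to 1.12%) and 0.663% of 142640 H2O2 reads (0.622 to 0.706%) were methylated, and at its 231 non-CpG cytosines 0.0720% and 0.0421%.

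CpGs at 20 to 60% methylation were lower in the H2O2 library by more than fully methylated ones. More complete conversion of methylated cytosines is argued against, since the ratio of H2O2 to control level was higher by 0.0300 (SE 0.00257) at 95% or more than at 20 to 60%. Fewer reads from methylated molecules with many CpGs is a candidate explanation, since the difference with 11 or more CpGs in the fragment exceeded that with 1 CpG by -2.87 points (SE 0.494). Such molecules keep more cytosines after bisulfite and may amplify less well, and the coverage of methylated over unmethylated CpGs fell in the same order, from 0.990 to 0.802 times the control value. The sizes did not match. With 11 or more CpGs this ratio would give -5.39 points, where -3.24 were measured, and it gave too much in each class above 1 CpG. Coverage also followed GC content, at 0.898 times the control below 50% GC and 1.08 times at 70% or more. Control levels there were 79.8% and 34.7%, so GC content and methylation cannot be told apart in the ratio. A loss of methylation after H2O2 stays open, since the difference in fragments with 1 CpG was -0.371 points (SE 0.247) and treatment is confounded with library.

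Read-weighted levels differed between the libraries more than levels of single CpGs did. For the pooled reads, most of the difference was a shift of coverage between CpGs of different methylation. With control coverage as weights for both libraries 6.12% of it was left, and with H2O2 coverage -0.191 of -3.11 points. What caused the coverage to shift was not settled. Inside windows the same shift leaves part of the calls unexplained, since 46.5% of called windows were also called with each CpG weighted alike, between the bounds set for either outcome. A difference of the cells that both strands share is argued against as the main source: the upper 95% limit of the covariance of CpG strand differences was 0.346 squared points (1.06 over the fewer CpGs with at least 20 reads per strand, just above the bound of 1), and windows called on the plus strand had -0.0132 times that difference on the minus strand (0.408 times where differences shared by both strands were simulated, so the bound set for a shared difference was hard to reach). Few template molecules per strand, amplified many times, might give such calls on a single strand, but the files hold no molecular identifiers and this was not tested.

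Outside CpGs, 15946 cytosines had at least 10% methylated reads, with mean levels of 48.6% in the control and 47.1% in the H2O2 library. A base change that turns CCH into a CpG in these cells was examined at the 4900 CCH sites among them. The coverage of the next cytosine relative to their own was 1 times that at low sites. This could not come out otherwise at 2869 of the sites, CCC cytosines 1 base inside a fragment end. There the next cytosine belongs to the MspI site, which must be intact to be cut. The remaining CCH sites were not examined apart from these, so the value decides nothing for them. Coverage of the next cytosine was under 0.25 at 7.51% of high sites and at 0.0238% of low sites. At the 2265 sites with a level of at least 50% this share was 14.7%, and a base change stays open for that part. For CCC cytosines, reads that start or end at an MspI cut are a candidate source. Of the 3749 high CCC sites 76.5% lay 1 base inside a fragment end, against 12.8% of other CCC sites, and CCC cytosines there had levels of 1.08% and 1.12% against 0.0660% and 0.0615% elsewhere, but the bound set for the excess was out of reach at these shares, so the test decides nothing. No biological explanation was tested for these sites, whose levels had r = 0.901 between the libraries.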
